A study of Caenorhabditis elegans with 5 samples.

How the data were processed

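The data were peak lists from ChIP-seq of tagged ATTF-4 in whole L4 larvae, made from 5 libraries of 3 replicates that the labels number as biological. The labels give attf-4 as the antibody target and pooled sexes. Per the deposited file notes, each replicate list was made from an alignment per biological replicate, which its technical libraries share, against a control, the pooled list was made from all 3 alignments with a control, and the final set was made from the pooled and replicate lists by the irreproducible discovery rate. The authors' lists give for each peak a signal value and a −log10 q-value, both as the deposited files hold them. Except for the final set, these lists hold background entries beside peaks, since they served to compute the irreproducible discovery rate. The aligner, the peak caller and their settings are not given in the sources used here. Lists on ce10 and ce11 were deposited, and coordinates were not converted between builds. The lists carry no read counts, so depth per library is unknown and no interval that needs it is given.

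The lists themselves were checked first. On ce11 all 173 final-set peaks were the 173 strongest peaks of the pooled list by signal. Every final-set peak carried the highest −log10 q-value of the deposited pooled list, 2.69, which 243 pooled peaks share, so ranks use the signal. Of the 24897 pooled intervals 24882 had a width of 320 bp. All ce11 peaks ended within the chromosomes of the reference (WBcel235, which is ce11), and all 7 chromosome names matched. Genes came from Ensembl annotation release 115, and mitochondrial genes without a name there took the RefSeq name of the gene they overlap. The ce10 lists were used without annotation, and their shifts and chromosome segments used the ce11 chromosome lengths.

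Peak positions are summits, counted from 1. A peak was shared where summits lay within 100 bp. Replicates were compared by the overlap of their 173 strongest peaks with 10000 circular shifts, and by correlation of signal over reciprocally nearest peaks with 100000 permutations. Final-set peaks were compared with 24696 lower-ranked pooled peaks whose summits lay over 500 bp from any final-set peak, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment in each family and a threshold of 0.05. A promoter ran from 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene. Classes were assigned in the order promoter, exon, intron, within 1000 bp downstream of a gene and other. Gene list tests used as background the 6446 genes with a pooled peak in the promoter window. GC was taken within 100 bp and 6-mers within 50 bp on each side of the summit, with reverse complements counted together. The attf-4 and unc-119 loci, of which transgenic strains of this kind carry extra copies, were compared with 10000 random nuclear windows. Odds ratio intervals are conditional 95% intervals and shares have 95% Clopper-Pearson intervals, and both cover counting error only.

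Genes were named by a rule set before the data were examined: those of the 25 strongest peaks, up to 4 members of each list with a final-set peak, and attf-4, unc-119 and the other attf genes. Genes named outside that rule, such as zfp-1, puf-9 and the additional ribosomal protein genes, were chosen after their values were seen. The tests and the first set of alternatives were also set before the data were examined. The values for nuclear peaks alone, for each replicate's own 173 strongest nuclear peaks and for GC-matched and equally many random peaks were added after the mitochondrial peaks had been seen.

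The 6-mer, gene list, overlap and GC comparisons were tested on simulated data, and the others were not. A 6-mer planted in 15% of peaks was called in 20 of 20 simulated sets for the 6-mer comparison over 2080 6-mers, and 1 of 20 sets without it gave any call. These sets were drawn from lower-ranked nuclear peaks, so they do not cover the GC difference of the final set. For the gene list comparison over 26 lists, 7 planted members were called in 20 of 20 sets, and 2 of 20 sets without them gave any call. The background of these sets was drawn at random from all protein-coding genes, not from genes with a pooled peak. The planted share of list members can therefore differ from the observed share, and these calls do not give the power at that share. For the overlap comparison all 34 planted shared peaks were found, but their summits were exact copies, so this outcome was fixed. A GC shift of 4 points was called in 20 of 20 sets, and 0 sets without a shift were called. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used, with a random seed of 11.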

Results

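ATTF-4 is a C. elegans protein with an AT-hook, a short motif found in proteins that contact DNA in the minor groove. Binding was mapped by ChIP-seq in whole L4 larvae, the last larval stage, of a strain that carries a GFP and FLAG tagged copy of the gene. The 5 libraries formed 1 group of 3 biological replicates, with 1 library for replicate 1 and 2 libraries each for replicates 2 and 3. Peaks had been called for each biological replicate, so the technical libraries of a replicate were not compared with each other. The question the design addresses is where the tagged protein is found in the genome and how far the replicates share those places. On ce11 the final set, defined by the irreproducible discovery rate (IDR), held 173 peaks, the list pooled over replicates held 24897 peaks, and the replicate lists held 30000, 22227 and 30000 peaks. The pooled and replicate lists include background entries by design, and the median −log10 q-value was 0.144 in the pooled list and 0.541, 0.579 and 0.213 in the replicate lists. The lower-ranked peaks used for comparison are therefore largely entries with little statistical evidence of binding. Signal values are the authors' peak caller's own, and peaks were ranked by them within a list. Read depth is not given in these lists and is unknown here.

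The strongest peaks lay on the mitochondrial genome. Of the 25 peaks with the highest signal, 23 were mitochondrial, and the mitochondrial genome of 13794 bp held 26 of the 173 final-set peaks. The strongest peak (ce11, mitochondrial genome, 13035 to 13289) had a signal of 849.9 and lay in ND5, which encodes a subunit of respiratory complex I. A peak at 12297 to 12667, also in ND5, had a signal of 765.5. The next lay in CYTB, the cytochrome b gene (4554 to 4866, signal 504.4), in COX2, a cytochrome oxidase subunit gene (10222 to 10303, signal 378.1), and in ND4, another complex I gene (7103 to 7422, signal 359.2). Further peaks among the 25 lay in or beside ND1, ATP6, COX3, COX1, ND2 and ND3. The rule for naming genes places several of these at the 5' window of the following gene, because mitochondrial genes lie close together. The highest signal of a nuclear peak was 94.2.

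The nuclear peaks among the 25 strongest were at pxn-1 and rpl-3, and both were found in all 3 replicates. The pxn-1 peak (ce11, chromosome V, 8500388 to 8500707) lay in an intron of this peroxidasin gene, within 200 bp of the snoRNA gene ZK994.7 and 5659 bp from the 5' end of pxn-1. The rpl-3 peak (chromosome III, 3867429 to 3867748, signal 82.5) had its summit 265 bp upstream of the 5' end of this ribosomal protein gene. Among the strongest nuclear peaks after these, chosen after their values were seen, were an exonic peak in pks-1 on X (5429392 to 5429711, signal 75.1), an intronic peak in frm-7 on V at the snoRNA genes C51F7.3 and C51F7.4 (signal 74.9), and the promoter of nspc-17 on X (signal 72.7). The gene zfp-1 on III held 3 intronic peaks, with signals of 71.0, 31.4 and 30.7.

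**Figure D1:**
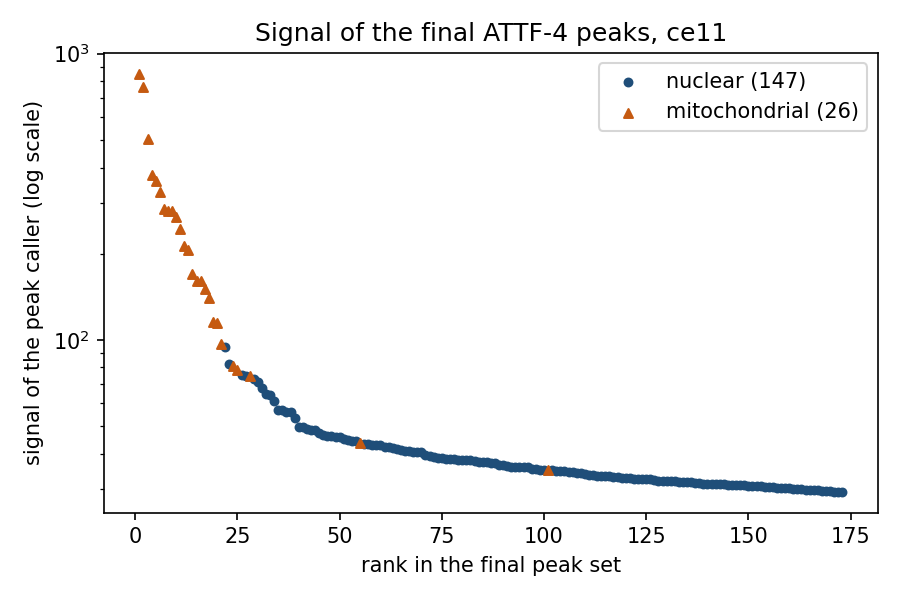
Signal of the peak caller on a log axis against rank for the 173 final-set peaks on ce11, with 26 mitochondrial peaks as triangles and 147 nuclear peaks as circles. The mitochondrial peaks reach 849.9 and the nuclear peaks 94.2.

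Replicates shared mitochondrial and nuclear positions, and the peaks in ND5 at ranks 1 and 2 and those at the promoters of rpl-3 and puf-9 were among the 1000 strongest of each replicate. Among the 173 strongest peaks of each replicate, 36 peaks of replicate 1 had a summit within 100 bp of replicate 2, 49 of replicate 1 within 100 bp of replicate 3, and 46 of replicate 2 within 100 bp of replicate 3. Nuclear peaks made up 20, 33 and 30 of these. The mean share was 25.2%, and it was 16.2% within 50 bp, 13.5% among the 500 strongest peaks and 10.3% among the 1000 strongest. Random circular shifts along the chromosomes gave 7.44, 9.01 and 9.46 shared peaks on average, and p was 1e-04 for each pair, the smallest that 10000 shifts allow (one-sided permutation test, adjusted p of 1e-04 over 3 pairs). Among the 173 strongest nuclear peaks of each replicate, compared after seeing the data, 21, 36 and 35 were shared, against 0.0702, 0.0666 and 0.0677 after shifts, with the same permutation p. The shifts do not hold peaks to open or readily mapped regions, so they cannot separate shared binding from shared background.

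The order of peak strength was compared across the same positions. Across matched peaks of the full lists, Spearman's rho was 0.166 for replicates 1 and 2 (2470 peaks), 0.211 for 1 and 3 (3671 peaks) and 0.192 for 2 and 3 (3350 peaks), each with a permutation p of 1e-05, the smallest that 100000 permutations allow, and an adjusted p of 1e-05 over 3 pairs. Pearson's r was 0.819, 0.823 and 0.816, with the same p; on nuclear peaks alone, an alternative chosen after seeing the data, r was 0.320, 0.411 and 0.409. For the nuclear final-set peaks rho was 0.108 (raw permutation p = 0.346, adjusted p = 0.374), 0.0857 (raw permutation p = 0.374, adjusted p = 0.374) and 0.289 (raw permutation p = 0.00445, adjusted p = 0.0133). For all final-set peaks, mitochondrial ones included, rho was 0.418, 0.279 and 0.463, with adjusted permutation p of 3e-05, 0.00209 and 3e-05, and r was 0.853, 0.830 and 0.847. These correlations run across peaks, which are not independent replicates.

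Replicate 3 held more of the final set than replicates 1 and 2. Among its 1000 strongest peaks 141 of the 173 final-set peaks had a summit within 100 bp (81.5%, 95% Clopper-Pearson interval 74.9 to 87.0%), against 98 for replicate 1 (56.6%, 48.9 to 64.1%) and 78 for replicate 2 (45.1%, 37.5 to 52.8%). All 3 replicates held 33 of the peaks (19.1%, 13.5 to 25.7%), among them those at rpl-3, rpl-20, rpl-15, puf-9, wwp-1, cebp-1 and mdl-1, and 118 were held by at least 2. Replicate 3 alone held 31, among them the promoter peaks of lgg-2, lin-23, cki-1 and rps-12. These counts cover the 1000 strongest peaks of each replicate. With all peaks of each list searched, 11 were found in replicate 3 alone and 153 in at least 2 replicates. The share held by every list rose to 44.5% without replicate 2 and 38.2% without replicate 1, and was 23.7% without replicate 3. Searching all peaks of each list gave 50.3%, a distance of 50 bp 9.83%, a distance of 200 bp 34.1%, any shared base 42.8%, and the 86 strongest final-set peaks 32.6%.

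**Figure D2:**
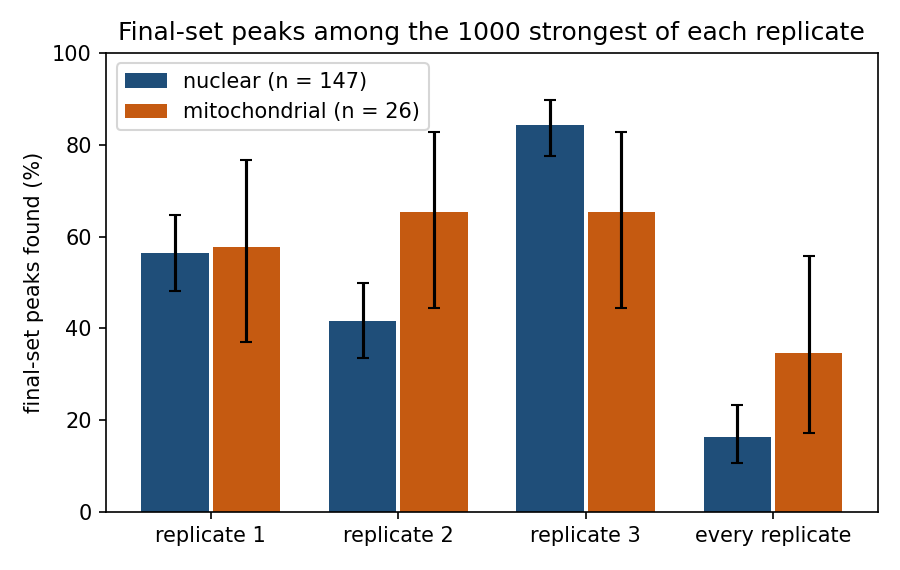
Share of final-set peaks with a summit within 100 bp among the 1000 strongest peaks of each biological replicate, in percent, for 147 nuclear and 26 mitochondrial peaks; error bars are 95% Clopper-Pearson intervals. Nuclear peaks were found at 84.4% in replicate 3 and at 41.5% in replicate 2.

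Nuclear peaks lay in promoters more often, and in exons less often, than lower-ranked peaks. Promoter windows, from 1000 bp upstream to 200 bp downstream of a protein-coding 5' end, held 81 of 173 final-set summits (46.8%) and 6322 of 24696 lower-ranked summits (25.6%), an odds ratio of 2.56 (95% interval 1.87 to 3.49, two-sided Fisher's exact test, raw p = 2.37e-09, adjusted p = 5.93e-09 over 5 classes). The 81 include mitochondrial summits, which such windows hold readily because mitochondrial genes lie close together. Without the mitochondrial peaks, a comparison chosen after seeing the data, the count was 61 of 147 (41.5%) and the odds ratio 2.06 (1.46 to 2.90, Fisher's exact test, raw p = 2.65e-05, adjusted p = 6.64e-05). Exons held 8 of 147 nuclear summits against 25.9% of lower-ranked ones, an odds ratio of 0.165 (0.0696 to 0.334, Fisher's exact test, raw p = 1.43e-10, adjusted p = 7.13e-10). Introns held 35 nuclear summits, including those in pxn-1, zfp-1, mef-2, lin-42 and daf-16. That was 23.8% against 27.3% of lower-ranked summits, which did not pass the test (odds ratio 0.832, 0.552 to 1.23, Fisher's exact test, raw p = 0.403, adjusted p = 0.403).

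The X chromosome carried 50 of the 173 peaks. That was 28.9% against 19.2% of lower-ranked peaks (odds ratio 1.71, 95% interval 1.20 to 2.39, Fisher's exact test, raw p = 0.00255, adjusted p = 0.00445 over 7 chromosomes), and 34.0% of the nuclear peaks (odds ratio 2.17, 1.51 to 3.08, raw p = 2.25e-05, adjusted p = 0.000135 over the nuclear chromosomes). X peaks included the promoters of puf-9, which encodes a Pumilio family RNA-binding protein, cebp-1, a bZIP transcription factor gene, and lin-14, a regulator of larval timing. Most X peaks lay outside promoters, which held 17 of 50 (34.0%) against 44 of 97 on autosomes (45.4%). That difference, not among the tests set in advance, did not pass (odds ratio 0.621, Fisher's exact test, p = 0.218). Chromosomes IV and V held 13 peaks each, with odds ratios by Fisher's exact test of 0.425 (raw p = 0.00120, adjusted p = 0.00279) and 0.361 (raw p = 6.99e-05, adjusted p = 0.000245). With mitochondrial peaks as a class, the odds ratio of the mitochondrial genome was 4368 (703 to 179064, Fisher's exact test, adjusted p = 2.1e-55), with 1 mitochondrial peak among the lower-ranked ones. Of the 28 pooled mitochondrial peaks 26 were in the final set. Neighbouring mitochondrial summits lay a median of 504 bp apart, so the 500 bp rule left little room for lower-ranked ones. This odds ratio therefore restates the signal ranking and that rule. Chromosomes I, II and III did not pass the test, with adjusted p of 0.672, 0.131 and 0.672.

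Autosomal peaks lay less often in the outer parts of the chromosomes. With each autosome divided into 3 equal segments, the outer segments held 44 of 97 final-set peaks (45.4%) and 58.9% of lower-ranked peaks, an odds ratio of 0.579 (95% interval 0.379 to 0.881, two-sided Fisher's exact test, p = 0.00936). Peaks at pxn-1, zfp-1, rpl-35 and lgg-2 lay in central segments, and those at rpl-3, rpl-20, rps-1 and cdc-48.1 in outer segments. The call was lost against the stronger 12348 lower-ranked peaks (odds ratio 0.659, Fisher's exact test, p = 0.0505), for the 86 strongest final-set peaks (0.558, p = 0.0901) and in replicate 2 alone (0.724, p = 0.0889).

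**Figure D3:**
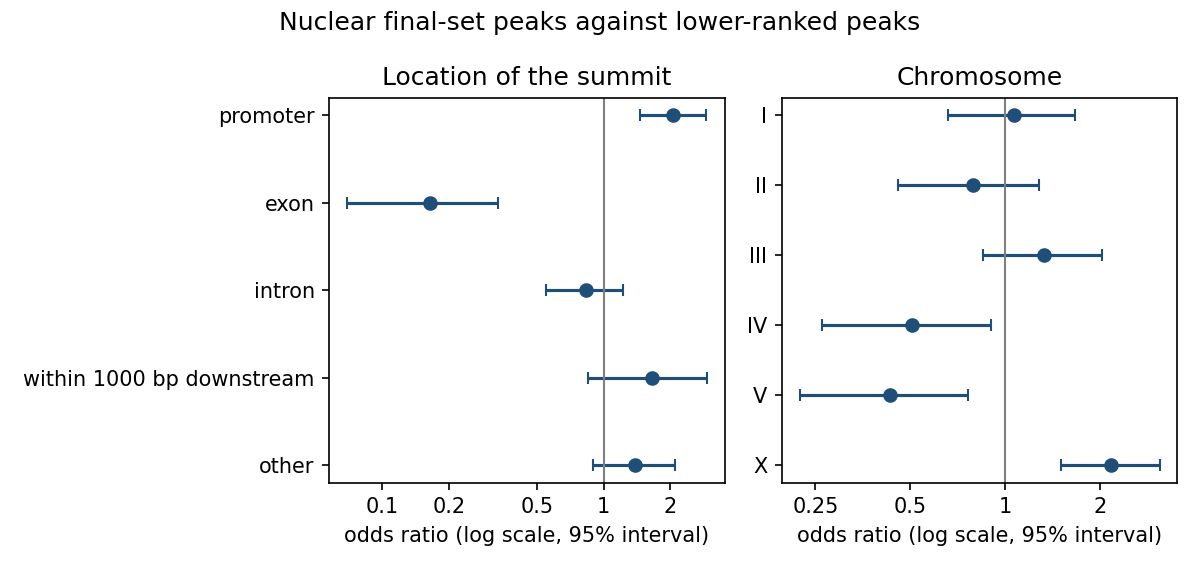
Odds ratios on a log axis for the location class and the chromosome of 147 nuclear final-set summits against 24695 lower-ranked nuclear summits, with 95% intervals. Promoters (2.06) and X (2.17) lie above 1, and exons (0.165), IV (0.508) and V (0.431) lie below 1.

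Ribosomal protein genes were the list that stood out among the 26 fixed lists. Of 67 ribosomal protein genes with any pooled peak in the promoter window, 7 had a final-set peak, against 89 of 6446 genes in all (odds ratio 8.96, 95% interval 3.35 to 20.4, two-sided Fisher's exact test, raw p = 3.35e-05, adjusted p = 0.000871 over 26 lists). They were rpl-3, rpl-20 (signal 67.6, summit 271 bp upstream), rpl-15 (53.2, 374 bp upstream), rps-1 (49.6, 230 bp upstream), rpl-35 (43.2), rpl-11.2 (34.8) and rps-12 (29.7). The rpl-20, rpl-15, rps-1 and rps-12 summits also lay in the promoter windows of the neighbours Y17G9B.5, K11H12.8, ifet-1 and ska-3. The summit was nearer to Y17G9B.5 (191 bp) than to rpl-20, and nearer to ska-3 (96 bp) than to rps-12 (197 bp). At rpl-15 and rps-1 it was nearer to the ribosomal protein gene. In the list of replicate 1 alone, an alternative chosen after seeing the data, the list no longer passed (odds ratio 7.04, Fisher's exact test, adjusted p = 0.0924), and it passed in replicates 2 and 3 (odds ratios 7.23 and 9.56). With every protein-coding gene as background the odds ratio was 22.9, and for the 86 strongest peaks it was 14.6.

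The other lists had at most 1 member with a final-set peak in the promoter window, the region these counts cover. Histones had 1 of 20 members (his-37, a histone gene on V, signal 31.6), nuclear hormone receptors 1 of 88 (nhr-49, a regulator of fat metabolism, 32.1), homeobox genes 1 of 28 (ceh-38, 40.5), heterochronic genes 1 of 5 (lin-14, 37.9), neuropeptides 1 of 37 (ins-39, an insulin-like gene, 39.2), chemoreceptors 1 member, or 0.426% (sre-23, 32.6) and F-box genes 1 of 61 (fbxb-58, 33.1). None of these 7 lists passed, with adjusted p of 0.873 by Fisher's exact test for the heterochronic genes and 1 for the others. The remaining 18 lists had no member with a final-set peak in the promoter window: collagens, major sperm proteins, vitellogenins, heat shock proteins, AT-hook genes, intestine, muscle, epidermis, pan-neuronal and germline markers, C-type lectins, translation factors, proteasome, vacuolar ATPase, cytochrome P450, glutathione transferases, signalling genes and insulin and stress factors. These lists had 3 to 61 members in the background, where 1.38% of all genes had such a peak. An absence of promoter peaks therefore carries little weight in any of these lists. Even for the largest, C-type lectins with 61 members, the upper limit of the odds ratio interval was 4.50. Outside promoter windows, members named after their values were seen included nhr-3, lin-42 and daf-16, with intronic peaks of signal 35.97, 31.5 and 38.1, and vha-8, the gene with the nearest 5' end to a peak of signal 32.7.

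Small RNA genes lay near many of the peaks. A snoRNA gene lay within 200 bp of 13 of 173 final-set summits (7.51%) against 0.599% of lower-ranked summits, an odds ratio of 13.5 (95% interval 6.86 to 24.4, Fisher's exact test, raw p = 1.11e-10, adjusted p = 2.77e-10 over 5 biotypes). Host or neighbouring genes of these snoRNAs included pxn-1, frm-7, cutl-18, wrt-3 and fars-1. Genes of tRNAs lay near 18 summits (10.4% against 1.36%, odds ratio 8.42, 4.80 to 13.9, Fisher's exact test, adjusted p = 2.77e-10), of which 8 were mitochondrial; on nuclear chromosomes the odds ratio was 5.29 (2.46 to 10.1, adjusted p = 0.000106). Genes of snRNAs lay near 3 summits, all of them sls-2 genes, which encode spliced leader RNA (odds ratio 10.1, 1.99 to 32.1, Fisher's exact test, raw p = 0.00403, adjusted p = 0.00504). The 4 summits near rRNA genes were mitochondrial, and miRNA genes did not pass (1 summit, at cel-mir-54, Fisher's exact test, raw p = 0.343, adjusted p = 0.343). In the list of replicate 2 alone, chosen after seeing the data, the tRNA odds ratio was 1.85 (Fisher's exact test, adjusted p = 0.283) and the snoRNA odds ratio 8.33. Against the stronger 12348 lower-ranked peaks the snoRNA odds ratio was 8.49 and the tRNA odds ratio 5.10.

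Nuclear summits were richer in GC than lower-ranked summits. GC within 100 bp on each side of the summit was 41.99% ± 10.1 (SD, n = 173 peaks) in the final set and 37.5% ± 7.15 (SD, n = 24696 peaks) in lower-ranked peaks, a difference of 4.48 points (two-sided permutation p of 1e-05, the smallest that 100000 permutations allow). The difference was 1.72 points within 250 bp and 6.02 points within 50 bp on each side. The 147 nuclear peaks had 44.9% ± 7.61 and the 26 mitochondrial peaks 25.7% ± 5.61. The mitochondrial genome as a whole had 23.8%, so its peaks lay near its own average. The nuclear difference, added after seeing the data, was 7.37 points, and it was 4.93, 4.50 and 8.71 points in the lists of replicates 1, 2 and 3 alone. Among promoter peaks it was 3.36 points with mitochondrial peaks included and 8.07 points for nuclear peaks. Among the 86 strongest final-set peaks, 25 of them mitochondrial, the difference was 1.31 points (permutation p = 0.0884), and among the 73 strongest nuclear peaks it was 6.68 points.

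**Figure D4:**
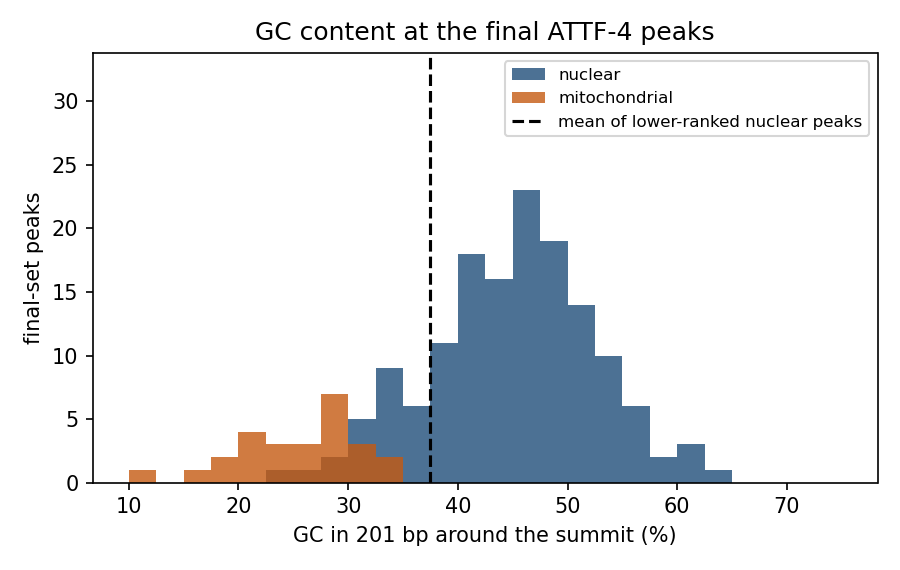
GC content within 100 bp on each side of each final-set summit, in percent, as counts of peaks for nuclear and mitochondrial peaks; the dashed line is the mean of lower-ranked nuclear peaks. The nuclear peaks centre on 44.9% and the mitochondrial peaks on 25.7%, on either side of the line at 37.5%. The mitochondrial genome as a whole has 23.8% GC.

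GC-rich 6-mers such as CCTGCG were more frequent at the summits, and A-rich ones such as AAAAAT were less frequent, though AAAAAT did not pass against peaks matched in GC content. Of 2080 6-mers, 167 passed an adjusted threshold of 0.05 within 50 bp on each side of the summit, 124 more and 43 less frequent in the final set. CCTGCG was present at 19 of 173 summits (11.0%) and 1.34% of lower-ranked summits (odds ratio 9.05, Fisher's exact test, raw p = 5.87e-12, adjusted p = 1.22e-08). By the same exact test CGTCTC was present at 29 summits (16.8% against 4.66%, adjusted p = 9.02e-07) and CGAGAG at 27 (15.6% against 3.99%, adjusted p = 6.97e-07). AAAAAT was present at 18.5% against 40.3% (odds ratio 0.337, Fisher's exact test, adjusted p = 5.92e-07). Against 2940 lower-ranked nuclear peaks matched in GC content (mean 44.8%), a comparison chosen after seeing the data, 32 6-mers passed, 29 more and 3 less frequent, where 224 had passed for nuclear peaks without matching, 174 more and 50 less frequent. In 20 random backgrounds of 2940 peaks without matching, 194 to 230 passed. The matched GC was that within 100 bp on each side of the summit, whereas 6-mers were counted within 50 bp. A GC difference within 50 bp may therefore remain after matching, so the 6-mers that passed cannot be separated from it. The less frequent ones after matching were GGAGCA, CGAGCA and AAAATC, while AAAAAT was present at 13.6% against 22.04% (odds ratio 0.557, Fisher's exact test, raw p = 0.0137, adjusted p = 0.221). Those more frequent after matching included, by Fisher's exact test, CCTGCG (12.9% against 2.35%, adjusted p = 1.32e-05) and CCCTGC (11.6% against 1.63%, adjusted p = 7.22e-06). These 6-mers overlap, so they are not separate results. At length 7, without GC matching, the sequence CCCTGCG that holds both was present at 12 of 173 summits. That was 6.94% against 0.223% of lower-ranked summits (odds ratio 33.4, Fisher's exact test, adjusted p = 1.54e-10).

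The locus of attf-4 itself, present in the strain also as a transgene, held more peaks than most windows of its size. The window of 20000 bp on each side of attf-4 (ce11, chromosome III, 6080563 to 6084748) held 23 pooled entries, background included, with a summed signal of 289.9, against a median of 10 peaks and 106.2 over 10000 random nuclear windows, which put it at percentile 98.9 by signal (p = 0.0111, one-sided, by permutation of the window's position). None was in the final set. The attf-4 promoter peak had a signal of 18.8, a −log10 q-value of 1.48 and rank 992, with its summit 88 bp upstream of the 5' end. With 10000 bp on each side the attf-4 window held 19 entries and the percentile was 99.7 (permutation p = 0.0032). With 40000 bp on each side the percentile was 94.0 (permutation p = 0.0603). The window of unc-119, the marker gene of such transgenes, held 12 peaks against a median of 11, and lay at percentile 46.8 by signal (permutation p = 0.532). Promoter windows of attf-2 and attf-3 each held 1 pooled entry at low significance (signals 15.8 and 9.22, −log10 q-values 0.909 and 0.133), and attf-5, attf-6 and unc-119 held none.

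The ce10 lists gave a final set of similar size. They held 171 final-set peaks and 28184 pooled peaks, with a median signal of 36.7 against 37.2 on ce11. X carried 51 peaks on ce10 and 50 on ce11, and the mitochondrial genome 25 and 26. The mean replicate overlap within ce10 was 25.4%.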

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

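The comparisons of nuclear peaks alone, of single replicate lists, of the stronger nuclear peaks and of GC-matched or equally many random peaks were chosen after the results were seen. The size of the final set on ce10, 171 peaks, is counted with these later alternatives. Of the alternatives set in advance, 51 kept direction and side of the threshold or stayed within their range, 4 lost the call and 9 moved; of those added later, 32 kept, 3 lost the call and 2 moved. No value in either set reversed. Replicate overlap ranged from 20.8 to 28.3% and rho from 0.166 to 0.211 with each replicate left out, and overlap fell to 10.3% among the 1000 strongest peaks. The share of final-set peaks in every replicate moved to 9.83% within 50 bp, 34.1% within 200 bp, 42.8% for any shared base, 50.3% with all peaks of each list and 32.6% for the 86 strongest peaks, and ranged from 23.7 to 44.5% with each replicate left out. By construction the share rises with the distance, the number of peaks searched and fewer replicates. The odds ratio for outer autosome segments was 0.659 against the stronger lower-ranked peaks, 0.558 for the 86 strongest peaks and 0.724 in the replicate 2 list alone, each no longer past the threshold; the cause was not tested. The tRNA odds ratio was 1.85 in the replicate 2 list, and the gene list count was 0 in the replicate 1 list; the cause was not tested. The GC difference was 1.31 points for the 86 strongest peaks, 25 of which are mitochondrial. The number of 6-mers past the threshold was 26 for the 86 strongest peaks, against 167 as reported, and 76 of 8192 passed at length 7. Such counts depend on how many peaks and sequences are tested, so they do not measure the strength of enrichment. The cause was not tested. For nuclear peaks 224 6-mers passed, and 32 against GC-matched peaks, where random backgrounds of that size gave a median of 211. The attf-4 window was at percentile 99.7 with 10000 bp on each side. With 40000 bp on each side it was at percentile 94.0, no longer past the threshold, and the cause was not tested. Unknown read depth limits every comparison between replicates.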

Other observations

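The test of affinity for AT-rich DNA was chosen after its result was seen; the others were set before theirs, except that the second mitochondrial coverage value was added, and that test left undecided, after the first was seen. The nuclear promoters below were named after their values were seen, and no group of them was tested. Promoters of cox-5A and cox-5B, which encode cytochrome oxidase subunits, had signals of 38.6 and 37.5, atp-3, an ATP synthase subunit gene, 32.2, and ndub-8, a complex I gene, 29.95. The atp-3 and ndub-8 summits also lay in the promoter windows of F27C1.2 and cup-14. The ndub-8 peak was found among the 1000 strongest peaks of replicate 1 alone. The autophagy genes lgg-1 and lgg-2 had promoter signals of 33.7 and 43.3, with a further intronic peak of 42.3 in lgg-2. The lgg-2 promoter peak was found among the 1000 strongest peaks of replicate 3 alone. The promoters of cki-1, a cyclin-dependent kinase inhibitor gene, and lin-23 had signals of 30.4 and 33.3, and both were found among the 1000 strongest peaks of replicate 3 alone.

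Mitochondrial peaks led the final set. Affinity for AT-rich DNA in general would give nuclear peaks of lower GC, but their GC lay 7.37 points above that of lower-ranked peaks. That value cannot decide the question, because GC-dependent recovery in the libraries, left open below, could hide such an affinity. Extra copies of the whole mitochondrial genome stay open: the deposited intervals covered 45.7% of it, under the bound of 50% set in advance, but 13 of the 28 intervals were narrower than the usual 320 bp, down to 82 bp, and the same summits at that width covered 58.2%. The bound was therefore wrong for this list, since the outcome follows interval width. Summits agreed within 100 bp between replicates more often than after shifts, at 16 of 25, 20 of 25 and 18 of 24 against 8.75, 11.3 and 10.9. The mean one-sided shift p was 0.0046 over 3 replicate pairs (raw permutation p of 0.0011, 0.0023 and 0.0104). Binding, fragmentation or mapping could all give this agreement. It was partial: with all peaks of each list searched, 9 of 26 mitochondrial final-set peaks were found in every replicate and 3 in none. The control's own mitochondrial signal was not analysed here, and no biological explanation was tested.

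Higher GC at nuclear summits was not accounted for by promoters or small RNA genes. Outside promoters the difference was 7.06 points, and without peaks within 200 bp of small RNA genes it was 7.23 points. GC-dependent recovery in the libraries remains a candidate explanation: signal rose with GC across lower-ranked nuclear peaks too, with a Spearman rho of 0.110, barely past the bound of 0.1, and a Pearson r of 0.155 (permutation p of 1e-05 for both, the smallest possible); the same relation may also come from open chromatin. No biological explanation of the GC difference was tested.

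The X excess included the promoters of puf-9, cebp-1 and lin-14, but only 17 of the 50 X peaks lay in promoters. It was not accounted for by location class and GC, with a Mantel-Haenszel odds ratio of 2.00 (95% interval 1.41 to 2.84). Nor was it accounted for by tRNA genes: without peaks near them the odds ratio was 1.84 (1.24 to 2.68). More X than autosome DNA in the ChIP libraries than in the control stays open, because the median signal of lower-ranked X peaks was 1.024 times that of autosome peaks, between the bounds set in advance. No biological explanation of the X excess was tested. Peaks of other tagged factors were not analysed here, so whether these X, snoRNA and ribosomal protein loci are specific to ATTF-4 stays open.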
